A study of Mus musculus with 10 samples.

How the data were processed

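RNA of sorted CD4 T cells (TCR beta positive, Foxp3 reporter YFP positive) was sequenced from gut and spleen of C57BL/6 mice of 2 genotypes. Foxp3Cre-YFP mice served as controls (WT), and Maf was deleted in Foxp3-expressing cells of the others (Maf-KO). RNA had been prepared with an RNeasy Plus kit and libraries with a TruSeq RNA kit, per the labels. The 10 libraries form 4 groups, WT gut (2 libraries), Maf-KO gut (2), WT spleen (3) and Maf-KO spleen (3), taken from the sample labels. The labels number the replicates within a genotype and do not say that each number is a separate animal, so p values measure the spread between samples.

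The deposited count table holds raw read counts per Entrez gene, made by the authors from aligned reads and not normalised. It has 27179 genes. The submitters' processing notes name Subread, featureCounts and limma and the builds GRCm38 and mm10. The aligner version, annotation release and strand setting are not given in the sources used here. The deposited log2 files hold log2 FPKM values of 12252 genes per library, computed by the authors per kilobase and per total of the listed genes, with a small offset for genes without reads. Each library's log2 values matched its own column of counts best in 10 of 10 cases. Genes not listed in the log2 files held 2.67 to 5.68% of the counts. The log2 files omit all 260 immunoglobulin segments, the mitochondrial genes and all but 1 predicted gene with a Gm symbol. Counts were therefore used for the tests, and the log2 values as an alternative.

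Total counts per library were 8567035 to 13983965, and a floor of 3 counts corresponds to 0.215 to 0.35 counts scaled to the library total (CPM). Intervals and floors cover counting error only. Between replicates of a group the chi-square per degree of freedom was 14.8 to 35.1, so replicates varied by more than counting. Ribosomal protein genes took 0.475 to 0.761% and mitochondrial genes 0.537 to 0.993% of the counts. There were 852 entries without a symbol, with 0.173 to 0.203% of the counts, and they stayed in the library totals and tests. All 10 sample columns were used. Gene positions came from a RefSeq table of GRCm38, which held 25275 of the 27179 identifiers.

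Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr with the 4 groups (minimum count 10, minimum total 15), which left 13214. Library sizes were scaled by TMM (factors 0.887 to 1.12), and 1 quasi-likelihood model with a coefficient per group was fitted to all 10 libraries (common dispersion 0.0431, prior degrees of freedom 3.97). Each contrast of the coefficients was tested by the two-sided quasi-likelihood F test. P values were adjusted by Benjamini-Hochberg over all genes tested in the contrast, and a gene was called at an adjusted p under 0.05. The contrasts were Maf-KO against WT in gut and in spleen, gut against spleen in WT and in Maf-KO, and the difference of the genotype effects between tissues (interaction). The SE of a log2 fold change is its size divided by the square root of F. Means and SD are of CPM scaled with the TMM factors. For a group with all counts at 0 a fold is a bound against 3 counts over the group, and with 1 to 3 counts a ratio with its exact 95% counting interval. Such intervals and bounds hold for counting error only.

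Genes were named by a rule set before the data were examined. Maf came first, in every library. For the 2 genotype contrasts and for gut against spleen in WT the rule took up to 10 called genes per direction with the largest changes, a mean of at least 5 CPM in the libraries compared and no overlap between the groups. It added fixed genes (Foxp3, Il10, Ikzf2, Gata3, Il17a, Ifng, Cxcr5 and Ccr6) and, for each list described, up to 4 called members by adjusted p or, where none is called, up to 2 by unadjusted p. Predicted genes, ribosomal and mitochondrial genes and immunoglobulin and T cell receptor segments were left out of the largest changes. The same genes as in WT were used for gut against spleen in Maf-KO. Members beyond these are said to have been picked after their values were seen. Before the data were examined, 31 gene lists were fixed too, 22 for states and pathways of T cells and 9 for other cells that a sort could carry along. Maf is in no list. Some genes that the rule names and 1 of the 22 lists are not reported here. Lists were tested by camera of limma 3.58.1 on the edgeR object with the preset correlation of 0.01, adjusted over the 31 lists within a contrast. Camera with an estimated correlation and fry stood beside it. Camera compares a list with all other genes, and fry tests whether its genes move one way on balance. Members were also counted when adjusted over the list alone.

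The alternatives were another normalisation (DESeq2 size factors), no filter on low counts, DESeq2 1.42.0, limma-voom, limma-trend on the log2 values, tissue fits with the TMM factors left out of the counts or applied to the log2 values, fits to the groups compared alone, leaving out each library in turn, and blocks. With 2 libraries in a group, leaving 1 out leaves a lone library, which is assumed to vary like those of the other groups. The titles hold numbers that are shared by gut and spleen libraries within a genotype. Over 9284 genes, residuals from the group means correlated between the libraries of the 4 such pairs with r of 0.48, 0.43, 0.51 and 0.56, so the numbers were treated as pairs. They entered as an additive term for comparisons of tissues and as a random effect with limma-voom (consensus correlation 0.509). Genes are not independent replicates in these correlations. With 2 gut libraries per genotype, their residuals mirror each other, so the 4 values are not separate. Between different title numbers r reached 0.32, for WT spleen replicate 3 and Maf-KO gut replicate 2. Replicate numbers are shared between genotypes by number only (r of -0.09, -0.14 and -0.40 in spleen), and a block on them was run as an alternative.

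The procedure was tested on simulated data, negative binomial counts drawn with the means and dispersions of these libraries, with 50 changed genes per fold. In gut it recovered 5 of 50 genes changed 1.5-fold, 17 at 2-fold, 40 at 4-fold and 48 at 8-fold, with 12 false calls among 12853 unchanged genes. In spleen it recovered 5, 30, 41 and 41, with 9 false calls among 12818, and between tissues in WT 4, 23, 34 and 47, with 6 among 12771. Each run also held a list of genes raised 2-fold. The simulated genotype contrasts thus held more changed genes than were called in the data, 20 in gut and 2 in spleen. An adjusted p under 0.05 is easier to reach with more changed genes, so these recoveries may overstate those of the real genotype contrasts. In gut and spleen the false calls made up a larger share of the calls than the 0.05 aimed at. That holds even if every gene of the raised list was called. The runs were not repeated, so the size of this excess is uncertain. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.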

Results

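Regulatory T cells (Tregs) are CD4 T cells that express Foxp3 and restrain other immune cells. They were sorted from the gut (colon plus small intestine) and the spleen of control mice (Foxp3Cre-YFP, called WT) and of mice whose floxed Maf gene is deleted in Foxp3-expressing cells (Maf-KO). Maf encodes c-Maf, a transcription factor of the AP-1 family. The series asks what c-Maf does in Tregs for Th17 cells and IgA in the intestine. There were 2 WT gut, 2 Maf-KO gut, 3 WT spleen and 3 Maf-KO spleen libraries. RNA was sequenced and reads were counted per gene. The libraries held 8728874 and 9538182 counts in WT gut (replicates 1 and 3), 12909265 and 13983965 in Maf-KO gut (replicates 2 and 3), 10031707, 12225539 and 9888181 in WT spleen and 8577819, 8567035 and 9603171 in Maf-KO spleen (replicates 1, 2 and 3). Levels are group means of CPM, a count scaled to its library's normalised total, with the standard deviation (SD, n = 2 in gut and 3 in spleen). Log2 fold changes have their standard error (SE) beside them where it is given.

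The first comparison asks whether the deletion is seen in the RNA. Maf RNA was abundant in the control Tregs and close to the counting floor in every Maf-KO library. The protein-coding gene (Entrez 17132) lies on chromosome 8 from 115703253 to 115706894 (GRCm38). It had 859 and 918 counts in the WT gut libraries and 7 and 3 counts in the Maf-KO gut libraries. In spleen it had 337, 312 and 484 counts in WT and 2, 10 and 2 counts in Maf-KO. The mean level was 108 CPM (SD 0.475, n = 2) in WT gut, 0.424 CPM (SD 0.261, n = 2) in Maf-KO gut, 33.3 CPM (SD 11.3, n = 3) in WT spleen and 0.505 CPM (SD 0.517, n = 3) in Maf-KO spleen. Maf fell by 7.98 on the log2 scale in gut (SE 0.57, edgeR adjusted p = 4.512e-04) and by 6.04 in spleen (SE 0.46, edgeR adjusted p = 0.00188). The spleen call was not made by limma-voom, where the adjusted p was 0.0929 and, with title number as a random effect, 0.132. Over all alternatives it ranged from 1.939e-32 to 0.132. Foxp3, the factor that defines the lineage, did not pass in either tissue. Foxp3 averaged 181 CPM (SD 34.9) in WT gut, 193 CPM (SD 26.2) in Maf-KO gut, 126 CPM (SD 8.59) in WT spleen and 119 CPM (SD 4.57) in Maf-KO spleen.

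**Figure D1:**
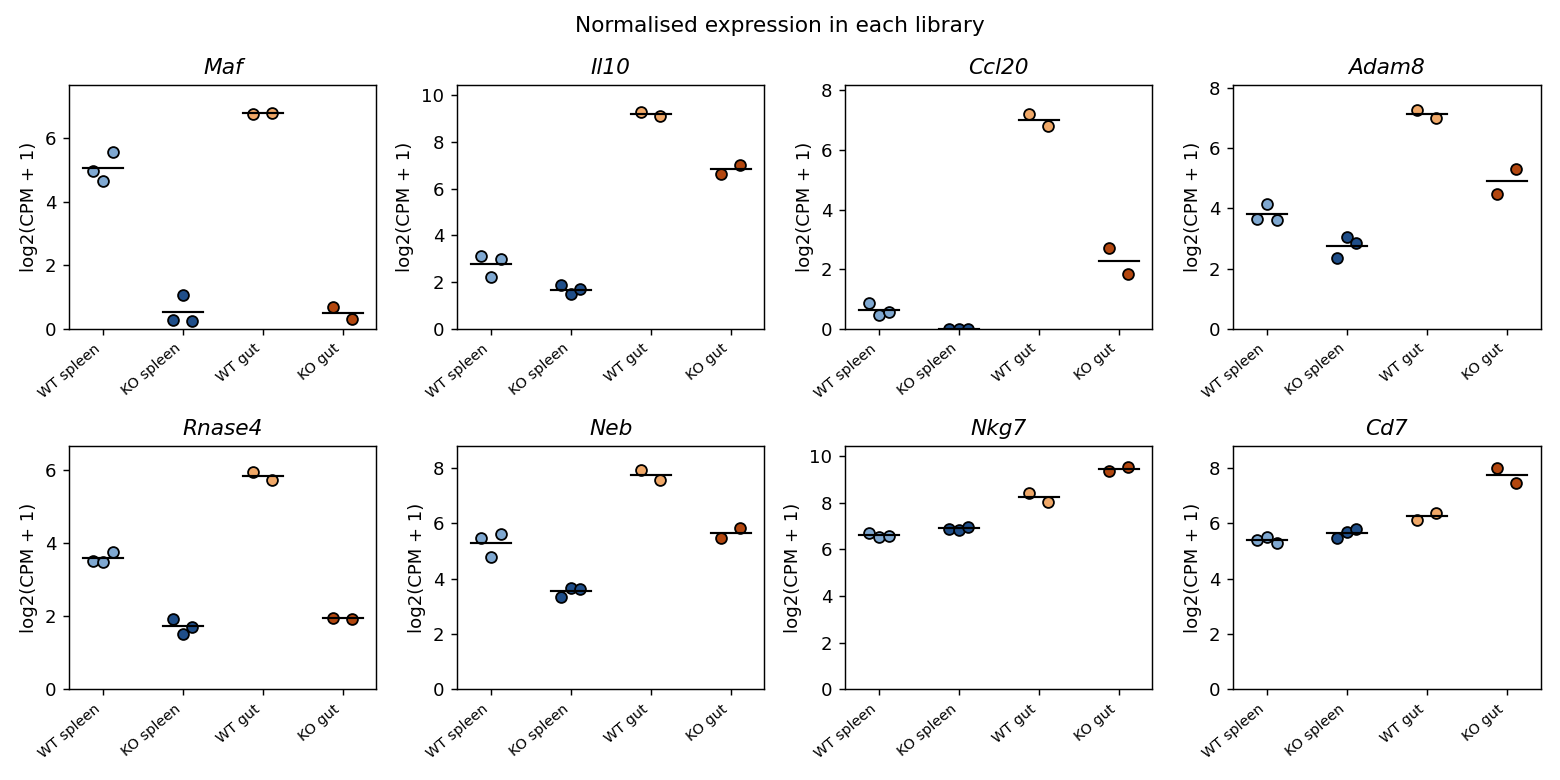
Each panel shows 1 gene as log2 of CPM plus 1 (vertical axis) in the 4 groups of libraries (horizontal axis), with a point per library and a line at the group mean. Maf, Il10, Ccl20, Adam8, Rnase4 and Neb sit lower in both Maf-KO gut libraries than in both WT gut libraries, and Nkg7 and Cd7 sit higher.

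What loss of c-Maf changes in intestinal Tregs is the main question of the series. In gut, Maf-KO Tregs carried less RNA for the anti-inflammatory cytokine gene Il10 and for Ccl20, whose product attracts CCR6-bearing cells. Rnase4 and Ang, neighbouring genes for secreted ribonucleases, were lower as well. The genes that rose were Nkg7, which encodes a membrane protein of cytotoxic granules, and Cd7, which encodes a surface protein of T and NK cells. Of 13214 genes tested with edgeR, 20 were called, 2 higher and 18 lower, and 1076 had an unadjusted p under 0.05. Fold changes of 2 or more were seen in 19 of the 20. In all 20 the 2 WT and 2 Maf-KO gut libraries did not overlap. Calling favours such genes, so this is no further support. For a gene not picked by its test, chance alone gives it in 2 of 6 arrangements.

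Il10 (Entrez 16153, chromosome 1 from 131019845 to 131024970) fell from 586 CPM (SD 43.2) in WT gut to 113 CPM (SD 20.8) in Maf-KO gut, a log2 change of -2.37 (SE 0.25, edgeR adjusted p = 0.0064). Ccl20 (Entrez 20297, chromosome 1 from 83116766 to 83119167) fell from 129 CPM (SD 26.5) to 4.02 CPM (SD 2.07), a log2 change of -5.01 (SE 0.38, edgeR adjusted p = 0.00473). Rnase4 (Entrez 58809, chromosome 14 from 51091077 to 51106151) fell from 55.8 CPM (SD 6.43) to 2.83 CPM (SD 0.0545), a log2 change of -4.29 (SE 0.24, edgeR adjusted p = 9.079e-05). Neb, the gene of the giant muscle protein nebulin, and its neighbour Arl5a, which encodes a small GTPase of the Golgi, changed by -2.13 (SE 0.26) and -1.75 (SE 0.22), each with an edgeR adjusted p of 0.0154. Adam8, a membrane metalloprotease gene, fell by 2.21 on the log2 scale (SE 0.32, edgeR adjusted p = 0.0342). Nkg7 (Entrez 72310, chromosome 7 from 43437138 to 43438246) rose from 302 CPM (SD 56.1) to 693 CPM (SD 61.4), a log2 change of 1.2 (SE 0.14). Cd7 (Entrez 12516, chromosome 11 from 121036747 to 121039478) rose from 75 CPM (SD 8.70) to 216 CPM (SD 58.6), a log2 change of 1.52 (SE 0.19), both at an edgeR adjusted p of 0.0154. Also lower were the pseudogene Hmga2-ps1 (-5.07), Matn2 of the extracellular matrix (-2.45), the FERM-domain gene Frmd5 (-2.13) and the lysosomal membrane gene Laptm4b (-1.64). The other 7 called genes, chosen for naming after their values were seen, were Col16a1 (-5.57), Ang (-4.65), Prg4 (-1.57), Snx2 (-1.18), Gpr155 (-1.10), Lrif1 (-1.09) and Mynn (-0.84). The gene models of Rnase4 and Ang overlap, so their counts may not be separate measurements.

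Maf, Rnase4 and Ccl20 kept their gut calls under all 19 alternatives tried. The other calls traced through the alternatives rested in part on single libraries. Il10 was at an adjusted p of 0.0986 without Maf-KO gut replicate 2 and 0.0574 without Maf-KO gut replicate 3, within 2.578e-17 to 0.0986 over its alternatives. Nkg7 was at 0.0825 without WT gut replicate 3, 0.0842 without Maf-KO gut replicate 2 and 0.127 without Maf-KO gut replicate 3, and ranged from 1.630e-11 to 0.175. Cd7 was at 0.191 without WT gut replicate 1, 0.0892 without WT gut replicate 3 and 0.0986 without Maf-KO gut replicate 2, and ranged from 1.129e-09 to 0.191. Neb lost its call without any 1 of the 4 gut libraries, with 0.137 and 0.0583 without WT gut replicates 1 and 3 and 0.185 and 0.127 without Maf-KO gut replicates 2 and 3 (range 4.814e-11 to 0.185). Arl5a was at 0.0825 without WT gut replicate 3 and at 0.185 and 0.159 without Maf-KO gut replicates 2 and 3 (range 1.984e-11 to 0.185). Adam8 was at 0.226 and 0.0987 without WT gut replicates 1 and 3, 0.191 and 0.06 without Maf-KO gut replicates 2 and 3, 0.0632 without WT spleen replicate 1 and 0.0654 without Maf-KO spleen replicate 3 (range 1.311e-08 to 0.226).

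Other calls depended on single libraries too. Hmga2-ps1 was at 0.207 and 0.0825 without WT gut replicates 1 and 3, 0.236 and 0.289 without Maf-KO gut replicates 2 and 3 and 0.0537 without WT spleen replicate 1 (range 3.186e-10 to 0.289). Leaving out any 1 library ended the call of Matn2 (adjusted p from 0.0529 to 0.321, over all alternatives from 4.090e-06 to 0.321). Frmd5 lost its call without any 1 library except WT spleen replicate 3 (highest adjusted p 0.33, lowest over all alternatives 3.278e-04). Laptm4b lost it without any 1 library except WT spleen replicate 3 and Maf-KO spleen replicate 1 (highest 0.241, lowest over all alternatives 1.017e-05). The number of genes called in gut was 7 without WT gut replicate 1, 5 without WT gut replicate 3, 4 without either Maf-KO gut replicate, 10 without WT spleen replicate 1 and 12 without Maf-KO spleen replicate 3. The genes called higher ranged from 0 without WT gut replicate 3 to 7 without WT spleen replicate 2 (13 lower), and DESeq2 called 36 higher and 76 lower. With the shared title number as a random effect it was 42, and this fit kept all 20 calls.

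Genes fixed for naming beforehand include markers of Treg subsets and helper cells. Ikzf2, which encodes Helios, changed by -0.49 (edgeR adjusted p = 0.632) and Gata3, the factor of Th2 cells and of a Treg subset, by -0.47 (edgeR adjusted p = 0.575). For the Th17 cytokine Il17a the change was 0.47 (edgeR adjusted p = 0.911), with 5.62 CPM (SD 3.43) in WT gut and 7.78 CPM (SD 4.36) in Maf-KO gut. Ifng, the Th1 cytokine, changed by 0.48 (0.81), the follicular receptor gene Cxcr5 by -0.40 (0.75), Ccr6 by 0.00 (1) and Foxp3 by 0.09 (0.928), all edgeR adjusted p values that did not pass.

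Read by list, the Th17 effector genes were lower as a set in Maf-KO gut (camera, adjusted p = 0.00107), with 1 of 11 members called over all genes (adjusted p = 0.758 with an estimated correlation). The members moved both ways, with 5 of 11 positive and a median of -0.64. When adjusted over the list alone, Ccl20 was among 2 members that fell, and 9 did not pass, among them Il17a, Il17f (0.18), Il22 (0.72) and Il1r1 (1.12). In the suppressive and effector Treg lists Il10 fell (4.207e-05 in each) and the other 17 of 18 members did not pass. Example members that were not fixed for naming, here and in the other comparisons of genotypes, were picked after their values were seen. Th1 effector genes moved both ways when adjusted over the list alone. Nkg7, Ccl5 (0.97), Tbx21 (0.49) and Cxcr3 (0.51) rose, whereas Il12rb2 (-1.99), Eomes (-2.28), Il18r1 (-0.82) and Stat4 (-0.35) were among 5 that fell, and 6 did not pass. By the same criterion Lrrc32, the Treg surface gene of GARP, rose by 1.54 (adjusted p = 0.016, over all genes 0.187) as the only 1 of 15 Treg identity genes. In the gut homing list Itga1 rose (1.32) and Ccr2 fell (-1.83), each at 0.0316. The kinase gene Pik3cd rose by 0.72 (0.00658) in the PI3K-Akt-mTOR list and the cytokine receptor gene Il21r by 0.90 (0.00343) in the STAT3 list.

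Smaller shifts spread over many members were called for 5 other lists by camera with its preset correlation. Cholesterol biosynthesis was higher (18 of 19 members positive, median 0.25, adjusted p = 0.0121, and adjusted p = 0.758 with an estimated correlation), with Lss (0.59) and Dhcr7 (0.38) as examples. Glycolysis was higher (13 of 18, median 0.14, adjusted p = 0.036), with Pfkp (0.42) and Slc2a3 (0.54), and so was oxidative phosphorylation (17 of 22, median 0.10, adjusted p = 0.0332), both at adjusted p = 0.758 with an estimated correlation. Immediate-early and heat shock genes were lower (1 of 18 positive, median -0.43, adjusted p = 0.0258, and adjusted p = 0.758 with an estimated correlation), with Ier3 (-1.18) and Dnajb1 (-1.20). Follicular helper and follicular regulatory genes were lower (3 of 15 positive, median -0.38, adjusted p = 0.0332, and adjusted p = 0.758 with an estimated correlation), with Sh2d1a (-0.69) and Btla (-0.53). No single member of these 5 lists passed in gut, over all genes or over the list alone. Pancreatic acinar genes were lower (adjusted p = 1.132e-09, and adjusted p = 0.505 with an estimated correlation), and all 5 tested members passed when adjusted over the list alone, 4 of them with 0 counts in Maf-KO gut. Pnlip, the pancreatic lipase gene, was at least 136-fold lower and the elastase gene Cela2a at least 119-fold lower, against 3 counts over the group.

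None of the gut list calls held with an estimated correlation, and leaving out libraries also ended calls. The Th17 list was at 0.123 without WT gut replicate 1 and 0.0742 without Maf-KO gut replicate 2. Cholesterol biosynthesis was at 0.242 without WT gut replicate 3 and 0.206 without Maf-KO gut replicate 3, oxidative phosphorylation at 0.727 and 0.349 and the immediate-early list at 0.751 and 0.206 without the same pair. Glycolysis was at 0.187 and 0.0533 without WT gut replicates 1 and 3 and 0.206 without Maf-KO gut replicate 3. The follicular list was at 0.254 without WT gut replicate 3, 0.187 without Maf-KO gut replicate 2 and 0.0503 without WT spleen replicate 1. The pancreatic list kept its call without any 1 library.

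Of the other lists none was called by camera in gut (7 of 31 were), and each of the following p values is adjusted. They include Treg identity (0.232), GATA3-positive and Helios-positive Treg (0.058), suppressive molecules (0.24), effector Treg (0.232), naive and lymphoid homing (0.0653), gut homing and residency (0.187), Th1 (0.509), Th2 (0.586), PI3K-Akt-mTOR (0.266), cell cycle (0.509), STAT3 and IL-10 family signalling (0.536), TGF-beta signalling (0.986), NF-kB (0.297), type I interferon (0.058) and aryl hydrocarbon receptor (0.936). The lists for other cells were B cell (0.626), plasma cell (0.266), gut epithelium (0.729), macrophage, monocyte and neutrophil (0.925), MHC class II (0.208), CD8, NK and innate lymphoid (0.143), red cell (0.0906) and stroma and endothelium (0.543). Of these, the suppressive, Th1, PI3K, cell cycle, STAT3, TGF-beta and macrophage lists had a median, a mean or a test direction of differing sign.

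Several of these lists were called without 1 library. The GATA3-positive list was lower without WT gut replicate 1 (0.0335), Maf-KO gut replicate 3 (0.0357), WT spleen replicates 2 (0.0337) and 3 (0.0452) or Maf-KO spleen replicates 1 (0.0353) and 3 (0.0375). Naive and lymphoid homing genes were higher without WT gut replicate 3 (0.00129), Maf-KO gut replicate 2 (4.696e-07) or Maf-KO spleen replicate 1 (0.0378). Cell cycle genes were higher without WT gut replicate 1 (0.00303) or Maf-KO gut replicate 3 (0.0357), and interferon genes without Maf-KO gut replicate 3 (0.0423) or Maf-KO spleen replicate 1 (0.0378). Without Maf-KO gut replicate 3 the effector Treg (0.00957) and stroma lists (0.00957) were lower and the B cell list higher (0.0357). The plasma cell list was lower without WT gut replicate 3 (0.00504) or Maf-KO gut replicate 2 (1.848e-04), the red cell list without Maf-KO gut replicate 2 (4.660e-04) and the epithelial list without WT gut replicate 3 (0.0227). The macrophage list was called without WT gut replicate 1 (0.04) and without Maf-KO gut replicates 2 (0.0104) and 3 (0.0255), with a reversed direction in the last.

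**Figure D2:**
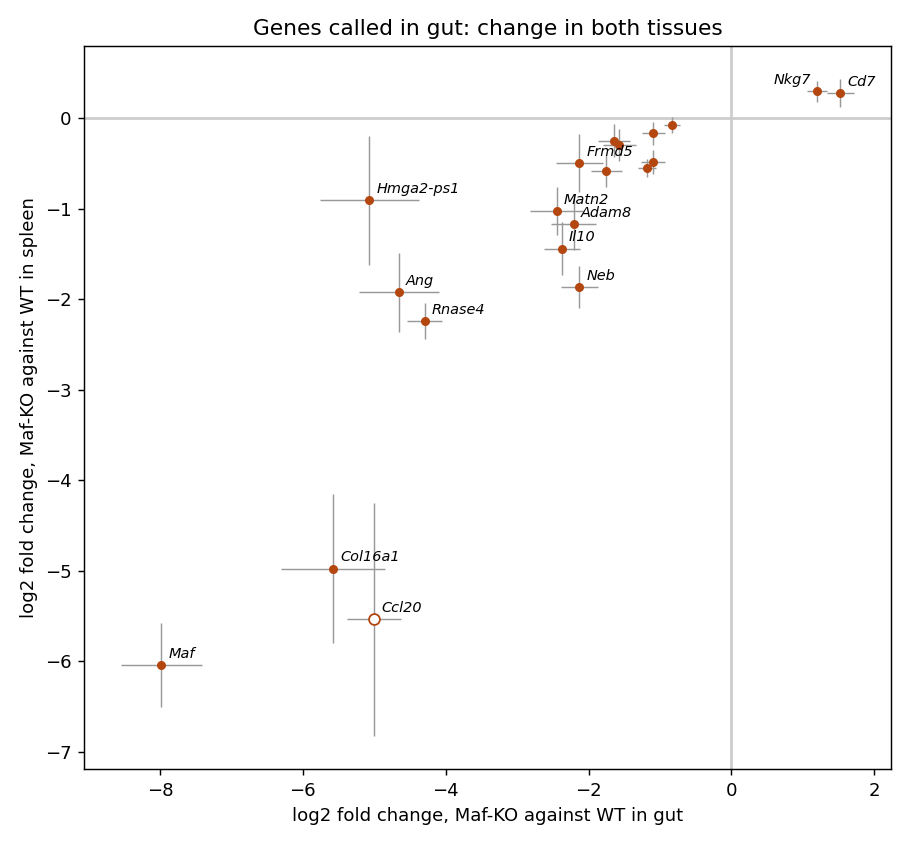
Log2 fold change between Maf-KO and WT in gut (horizontal axis) and in spleen (vertical axis) for the 20 genes called in gut, with a point per gene and bars of 1 standard error. All 20 have the same sign in both tissues, and the open point is Ccl20, whose spleen value depends on the prior count because Maf-KO spleen had 0 counts.

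In spleen, the genes that changed with genotype were Maf itself and Rnase4, 2 of 13214 tested with edgeR, with 376 at an unadjusted p under 0.05. Rnase4 averaged 11 CPM (SD 1.32) in WT spleen and 2.31 CPM (SD 0.478) in Maf-KO spleen, a log2 change of -2.24 (SE 0.20, edgeR adjusted p = 0.00312). Neb, at -1.87 (SE 0.23), lay just short of the threshold (edgeR adjusted p = 0.0512). Il10 was far less abundant than in gut, with 6.06 CPM (SD 2.09) in WT spleen and 2.20 CPM (SD 0.422) in Maf-KO spleen. Its change of -1.44 (SE 0.30) missed the threshold over all genes (edgeR adjusted p = 0.578). Il10 fell when adjusted over the list alone in the suppressive and effector Treg lists (0.0118 in each). Il10 passed without WT spleen replicate 2 (0.0311), with DESeq2 (0.00111) and without the low-count filter (0.042). Its highest adjusted p over the alternatives was 1. Rnase4 missed the threshold by limma-voom (0.0834), with title number as a random effect (0.132) and with spleen libraries alone (0.129), and ranged from 4.171e-13 to 0.132. Limma-voom called 0 genes in spleen, with 320 at an unadjusted p under 0.05. With title number as a random effect it called 0 as well, with 307 unadjusted. The count was 9 without WT spleen replicate 2.

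The other genes fixed for naming did not pass in spleen. Foxp3 changed by -0.07, Ikzf2 by -0.17, Gata3 by 0.21, Ifng by -0.18, Cxcr5 by -0.24 and Ccr6 by 0.18, and Il17a had 0 counts in all 6 spleen libraries. In the Th17 effector list, called lower as a set (camera, adjusted p = 0.0113, and adjusted p = 0.953 with an estimated correlation), Ccl20 and Il21 were among 3 members that fell when adjusted over the list alone (0.0148 and 0.0329). Il21 changed by -3.79 (SE 1.17, edgeR adjusted p = 0.999) at a mean of 2.72 CPM, and its WT and Maf-KO libraries overlapped. In this list 3 genes lay at the floor in both spleen groups, and 1 more had 0 counts in 1 group. Ccl20 had 19 counts over the WT spleen libraries and 0 in Maf-KO, at least 5.20-fold lower against 3 counts over the group. The T cell homing genes Itgae (1) and Cxcr6 (0.68) rose when adjusted over the gut homing list alone, each at 0.0352. Sh2d1a, the gene of the adaptor SAP, fell by 0.79 on the log2 scale in the follicular list (adjusted over the list alone, 0.0145), which was lower as a set (3 of 15 positive, camera, adjusted p = 0.0113, and adjusted p = 0.953 with an estimated correlation). Socs3, a feedback inhibitor of STAT3, fell by 0.87 on the log2 scale (adjusted over the list alone, 0.042) within the STAT3 and IL-10 family list, also called lower (3 of 12 positive, camera, adjusted p = 0.0206, and adjusted p = 0.953 with an estimated correlation). Igha, the IgA heavy chain gene, rose when adjusted over the plasma cell list alone (0.0246, over all genes 0.999). Its level was 32.0 CPM (SD 11.7) in WT spleen and 108 CPM (SD 12.3) in Maf-KO spleen, which an exact two-sided permutation test put at p = 0.1, the smallest 3 against 3 can give. Macrophage, monocyte and neutrophil genes were lower as a set (1 of 15 positive, median -0.45, camera, adjusted p = 0.0199, and adjusted p = 0.953 with an estimated correlation).

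These 4 spleen list calls did not hold with an estimated correlation, and single libraries decided them. The Th17 list was at 0.0532 without Maf-KO spleen replicate 3. Follicular genes were at 0.385 without WT spleen replicate 3 and 0.0833 and 0.102 without Maf-KO spleen replicates 2 and 3. The STAT3 list was at 0.173 and 0.0697 without WT spleen replicates 2 and 3 and 0.121 without Maf-KO spleen replicate 2. The macrophage list was at 0.279 and 0.358 without Maf-KO spleen replicates 1 and 3, and without WT spleen replicate 3 its mean log2 change turned to 0.18 (0.971). The other 27 lists were not called in spleen. Some were called without 1 library: Treg identity lower without WT spleen replicate 1 (0.0174), effector Treg (0.0368), immediate-early (0.0368), naive (0.0368), MHC class II (0.0183) and CD8 and NK genes (0.00379) without Maf-KO spleen replicate 2, and red cell (0.049) and TGF-beta genes (0.0403) without WT spleen replicate 2. Cholesterol genes were called without WT spleen replicate 2 (9.614e-08) or Maf-KO spleen replicate 2 (0.0337), and B cell genes without the same libraries (0.0268 and 5.503e-12). NF-kB genes were called without Maf-KO spleen replicate 1 (0.00583) or WT spleen replicates 1 (0.0174) and 2 (0.0195), and interferon genes without Maf-KO spleen replicate 1 (5.323e-04) or WT spleen replicate 3 (0.0411). Cell cycle genes were called lower without WT spleen replicate 3 (0.0189) and higher without Maf-KO spleen replicate 3 (0.0159), and the pancreatic list without WT spleen replicate 1 (0.00625) or Maf-KO spleen replicate 2 (0.0366). The suppressive, PI3K, cell cycle, TGF-beta and immediate-early lists had a median, a mean or a test direction of differing sign.

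Maf and Rnase4 were lower in both tissues. Maf is lower in both by design, and without it the overlap is Rnase4, 1 gene against 0.00129 expected from 17 gut and 1 spleen call without Maf (Fisher's exact test, p = 0.00129, chosen after the calls were seen and treating genes as independent). The comparison shares animals as far as the title numbers tell, since 2 title numbers per genotype gave both tissues. All 20 gut calls had the same sign in spleen, Maf included, and 13 of them had an unadjusted spleen p under 0.05. Residuals of libraries with a shared title number correlate, so some agreement is expected without a shared response. In the 2 spleen libraries that share no number with gut, Maf-KO replicate 1 and WT replicate 2, a check chosen after the results were seen, 18 of 19 gut calls without Maf kept their sign (17 of 17 lower and 1 of 2 higher, with 50.2% of all tested genes lower). That is 1 library per genotype, and the genes are not independent. The same 13 of 20 passed in spleen when adjusted over those 20 genes alone, a list picked from the gut libraries. The overlap was 7 without WT spleen replicate 2. With edgeR 0 genes were called for a difference of the genotype effect between the tissues, with 422 at an unadjusted p under 0.05, while DESeq2 called 8 and limma-voom and limma-trend called 0. The smallest p in this test was that of Rnase4, whose fall was larger in gut (interaction -2.05, edgeR adjusted p = 0.605). When adjusted over their lists alone, Nkg7 (0.90, adjusted p = 0.00937), Il21r (0.96, 0.0131) and Il12rb2 (-1.85, 0.0395) differed between tissues. By the same criterion so did all 5 tested pancreatic acinar genes, each with a negative difference. For Il10 the interaction was -0.93 (edgeR adjusted p = 1). Camera called 6 lists for this difference with its preset correlation, each of which lost its call without at least 1 library, and 0 with an estimated correlation (lowest adjusted p = 0.322).

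The tissue comparison asks how gut Tregs differ from splenic ones, first in WT. In either genotype, effects of the tissue and of preparing cells from that tissue cannot be told apart in this design. Il10, the wound-repair growth factor gene Areg and the granzyme gene Gzma were among the genes most raised in gut over spleen. Tcf7, a factor of naive and memory T cells, was lower in gut. The chemokine receptor genes Ccr9 and Cxcr6, which direct cells to small intestine and other tissues, were higher, and so was Maf (1.70, SE 0.33, edgeR adjusted p = 0.00388). Of 13214 genes tested with edgeR 3703 were called, 1942 higher and 1761 lower in gut, and 1936 changed 2-fold or more. In 3696 of them the 2 gut and 3 spleen libraries did not overlap. Chance alone gives this for 20% of genes not picked by their test, and calling favours such genes, so the count is no further support. The first principal component held 64.4% of the variance and parted the tissues, and the second held 8.27%.

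The deposited log2 FPKM values, tested with limma-trend, gave a median change of all genes of -0.29 and a split of 1163 higher and 3698 lower. In the count-based fit this median was -0.03. The difference follows the scaling, as shown by 2 fits added after the results were seen. Counts without TMM factors gave a median of -0.30 with 1327 higher and 3938 lower by edgeR, and the log2 values less the TMM factors gave -0.03 with 1773 higher and 1703 lower. TMM takes most genes as unchanged, which these data do not test, so the balance of higher and lower genes depends on that choice. The number called was 2183 without WT gut replicate 1. With the title number as a block it was 4913, and as a random effect 5498.

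Il10 averaged 586 CPM (SD 43.2) in WT gut against 6.06 CPM (SD 2.09) in WT spleen, a log2 change of 6.61 (SE 0.26, edgeR adjusted p = 2.549e-07). Areg averaged 618 CPM (SD 22.0) against 6.19 CPM (SD 0.813), and rose by 6.64 (SE 0.24, edgeR adjusted p = 1.782e-07). Gzma averaged 2742 CPM (SD 185) in gut and 12.4 CPM (SD 6.18) in spleen and rose by 7.79 (SE 0.61, edgeR adjusted p = 1.682e-05). Ccl20 rose by 7.85 and Ahrr, the repressor of the aryl hydrocarbon receptor, by 7.65. Heat shock genes of the Hsp70 family led the list, Hspa1a with 11.17 (SE 1.49) and its near-identical copy Hspa1b with 9.85 (SE 1.72), for which reads cannot be assigned with certainty and DESeq2 gave no p value. The stress factor gene Atf3 rose by 7.10. Rbm24, an RNA-binding protein gene, had 514 gut and 2 spleen counts, a ratio of 544 (95% counting interval 150 to 4508). The pancreatic genes Pnlip and Cela2a were also among the 10 largest, Pnlip at a ratio of 197 (66.7 to 961) and Cela2a at 6.89, and Cela2a lost its call without WT gut replicate 1 (0.0842). With DESeq2 Pnlip (0.132, range 3.498e-05 to 0.132) and Cela2a (0.199, range 1.490e-04 to 0.199) were not called.

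Genes lower in gut included several of macrophages and neutrophils. Cd5l, a macrophage gene, had 399 spleen and 0 gut counts, at least 62.8-fold lower against 3 counts over the group. The neutrophil genes S100a8 (-8.09), S100a9 (-7.85) and Ngp (ratio 288, interval 51.5 to 11391) rested on few libraries. WT spleen S100a8 was 120 CPM (SD 174, n = 3). Without WT gut replicates 1 and 3 in turn, the adjusted p was 0.165 and 0.118 for S100a8, 0.166 and 0.116 for S100a9 and 0.0881 and 0.0901 for Ngp. By limma-voom these genes were at 0.396, 0.385 and 0.176, and with title number as a random effect at 0.202, 0.203 and 0.0782. Fcna had a ratio of 258 (46.1 to 10198) and Fut7, a fucosyltransferase gene, of 78.8 (21.7 to 654). Slc40a1, the iron exporter gene, fell by 5.25, Dapl1 by 4.74 and Sema4a by 4.40, each on the log2 scale.

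By list, camera called the gut homing and residency genes, with 13 of 15 higher (median 2.58, adjusted p = 3.904e-22), among them Ccr9 (5.96), Rgs2 (4.52), Cxcr6 (4.40) and Gpr55 (3.75). NF-kB genes were higher in 9 of 12 (median 1.33, adjusted p = 5.747e-21), such as Tnfaip3 (4.74) and Rel (3.54). Immediate-early and heat shock genes were higher in 16 of 18 (median 2.89, adjusted p = 1.390e-17), such as Fosb (5.66) and Nr4a1 (4.75). Effector Treg genes were higher in 15 of 18 (median 1.99, adjusted p = 1.769e-16), with Gzmb (6.12), Id2 (3.47) and Irf4 (2.01). In the suppressive list 11 of 18 were higher and 0 lower (edgeR; median 1.33, adjusted p = 2.426e-14), with Ctla4 (3.71) and Fgl2 (3.36). GATA3-positive and Helios-positive Treg genes were higher in 9 of 11 (median 1.59, adjusted p = 7.726e-08), with Nfil3 (4.17) and Gata3 (2.22), while Nrp1 fell (-2.53).

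Th17 genes were higher in 10 of 11 (median 4.80, or 4.78 with genes at 0 set to their bound; adjusted p = 1.065e-11). Il17a had 91 gut and 0 spleen counts, at least 64.3-fold higher, and Il22 186 and 1, a ratio of 394 (69.9 to 15647). Th1 genes were higher in 12 of 15 (median 1.64, adjusted p = 2.147e-10), with Hopx (1.83) and Nkg7 (1.64), and Th2 genes in 4 of 6 (median 1.71, adjusted p = 1.314e-04), with Ccr8 (2.51) and Ccr4 (1.56). Aryl hydrocarbon receptor genes were higher in 3 of 6 (median 1.25, adjusted p = 1.018e-06), with Ahrr and Tiparp (2.64). These 10 lists, from gut homing to the aryl hydrocarbon receptor, held with an estimated correlation (adjusted p from 0.0037 to 0.0457).

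Naive and lymphoid homing genes were lower in 14 of 17 and higher in 0 by edgeR (median -1.97, adjusted p = 1.556e-12, 0.132 with an estimated correlation). Tcf7 (-2.34), Bcl2 (-2.31), Id3 (-2.92) and S1pr1 (-2.77) were examples. TGF-beta genes were mostly higher (7 of 13, adjusted p = 3.266e-04, 0.194 with an estimated correlation), with Furin (2.35) and Skil (1.83). Cholesterol genes were higher in 6 of 19 (adjusted p = 0.00147, 0.548 with an estimated correlation), with Insig1 (2.37) and Cyp51 (1.94). Type I interferon genes were lower in 8 of 15 and higher in 2 (adjusted p = 0.0154, 0.512 with an estimated correlation), with Usp18 (-3.20) and Ifit3 (-1.95) lower and Isg15 (1.35) higher. Glycolysis genes were higher in 5 of 18 and lower in 2 (adjusted p = 0.0395, 0.423 with an estimated correlation), with Hk2 (1.56) and Aldoa (0.75). The glycolysis call ended without WT spleen replicate 1 (0.108) or WT gut replicate 3 (0.125). Treg identity genes were higher in 7 of 15 and lower in 4, with Itgae (2.90) and Capg (1.29) higher and Gpr83 (-2.54) lower. That list was not called (0.0517), but was without WT gut replicate 1 (0.0208), WT spleen replicate 3 (0.044) and Maf-KO spleen replicates 1 (0.0287) and 2 (0.0137). Fry called the naive (adjusted p = 0.00151) and interferon lists (0.0314) lower. It called the TGF-beta (7.475e-04), cholesterol (0.0378), glycolysis (0.00614) and Treg identity lists (0.0282) higher. Camera did not call the follicular (0.261), oxidative phosphorylation (0.892), PI3K (0.751), cell cycle (0.768) and STAT3 (0.542) lists, and neither did fry. The PI3K and STAT3 lists had a median and a mean of differing sign.

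RNA typical of other cells also differed between WT gut and spleen. Plasma cell genes were higher in 8 of 10 (camera, adjusted p = 1.802e-05, 0.238 with an estimated correlation), with Igha (8.18), Jchain (5.73), Igkc (4.38) and Sdc1 (4.30). B cell genes were lower in 10 of 14 and higher in 1 (camera, adjusted p = 9.941e-05, 0.423 with an estimated correlation), with Cd22 (-2.94) and Spib (-3.39). Epithelial genes were higher in 3 of 9 (camera, adjusted p = 0.0197, 0.406 with an estimated correlation), with Krt18 (2.70) and Epcam (1.78). Epcam was present in every library, at 29.9 to 63.8 CPM in spleen and 119 to 167 CPM in gut. Fabp1 of the same list had at most 12 counts in a library. Which cells held the Epcam RNA was not tested. Pancreatic genes were higher in 5 of 5 (camera, adjusted p = 0.0114, 0.423 with an estimated correlation). Without WT gut replicate 1 the epithelial list was at 0.0952 and the pancreatic list at 0.0633. Fry called the plasma cell (adjusted p = 0.00629), B cell (0.0282), epithelial (0.0095) and pancreatic lists (0.0196) in the same directions as camera. Not called by camera were the macrophage (0.298), MHC class II (0.542), CD8 and NK (0.542), red cell (0.606) and stroma (0.751) lists, and fry did not call them. The CD8 and stroma lists had a test direction that differed in sign from their median. With the title number as a block the macrophage list was called lower in gut (3.688e-06 in WT and 0.00772 in Maf-KO). Immunoglobulin genes took a mean of 2.41% of the counts in WT gut (SD 1.24, n = 2) and 1.62% in Maf-KO gut (SD 1.13, n = 2), against 0.182 to 0.351% in the 6 spleen libraries. The immediate-early and heat shock list took 3.32% in WT gut (SD 1.33) and 2.18% in Maf-KO gut (SD 0.462), against 0.348 to 0.589% in spleen. Whether this RNA rose in the tissue or while cells were prepared was not tested.

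**Figure D3:**
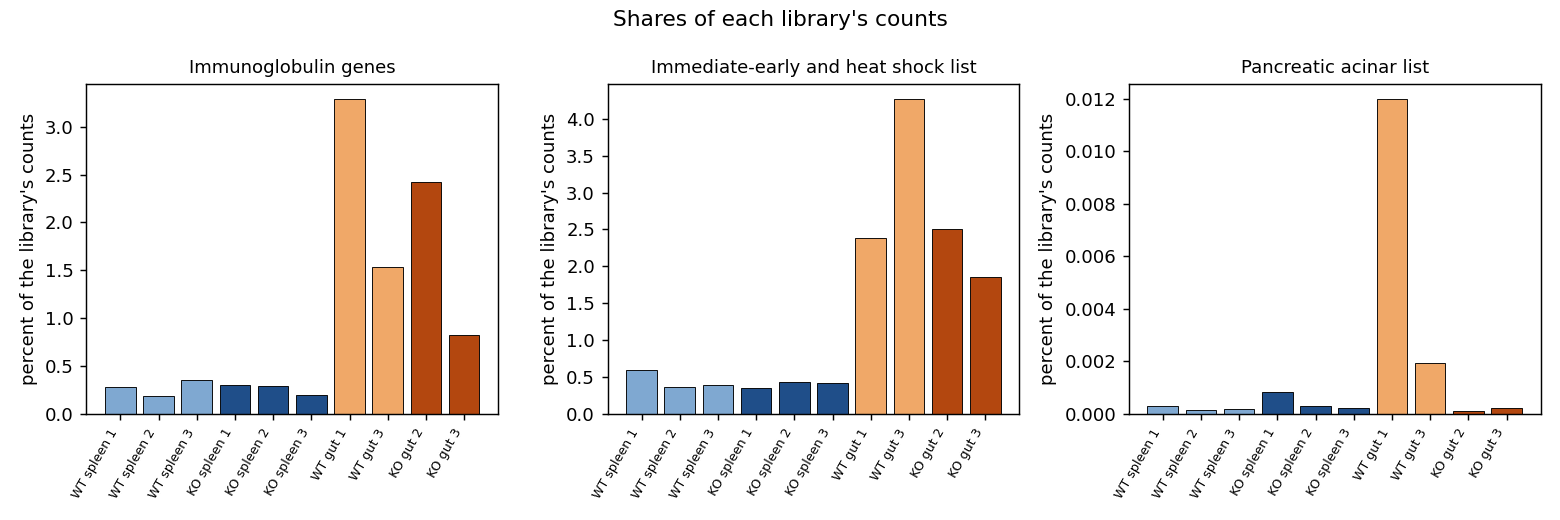
Percent of each library's counts (vertical axis) taken by immunoglobulin genes, by the immediate-early and heat shock list and by the pancreatic acinar list, with a bar for each of the 10 libraries (horizontal axis) coloured by group. The first 2 shares are higher in every gut library than in every spleen library, and the pancreatic share is highest in WT gut replicate 1.

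In Maf-KO mice, gut Tregs differed from spleen Tregs in largely the same genes. Il10 was still higher in gut, by 5.67 (SE 0.28, edgeR adjusted p = 9.834e-07), as were Areg (6.63), Gzma (8.70), Ccr9 (5.69), Cxcr6 (3.46), Ctla4 (4.09) and Foxp3 (0.69). Tcf7 (-2.19) and Nrp1 (-1.92) were lower. Rnase4, higher in gut by 2.34 in WT (edgeR adjusted p = 1.946e-05), did not pass in Maf-KO (0.29, edgeR adjusted p = 0.391), and neither did Maf (-0.23, edgeR adjusted p = 0.87). Of 13214 genes tested with edgeR 3774 were called, 1906 higher and 1868 lower, with 1929 changed 2-fold or more. Of these calls 3766 had no overlap, which calling favours (20% by chance for genes not picked by their test). Of the genes called in WT and in Maf-KO, 2825 were called in both with the same direction, against 529 expected if independent, and 1 in opposite directions. Across genes the log2 changes of the genotypes had a Pearson r of 0.87, and genes are not independent replicates. The number called was 2118 without Maf-KO gut replicate 3 and 2394 without Maf-KO gut replicate 2. With the title number as a random effect it was 5778, and as a block 5244. Limma-trend on the deposited log2 FPKM values gave a median change of -0.27 and 1082 higher against 3442 lower genes, and less the TMM factors -0.01 with 1751 against 1741.

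Most of the lists called in WT were called in Maf-KO too. Camera called higher, also with an estimated correlation (adjusted p from 0.00192 to 0.0464), the gut homing (11 of 15 members higher, 2.411e-20), NF-kB (10 of 12, 2.584e-21), immediate-early and heat shock (14 of 18, 3.246e-15), suppressive (11 of 18, 5.586e-13), Th1 (11 of 15, 2.795e-11) and Th17 lists (10 of 11, 1.205e-09). Effector Treg (13 of 18, 2.115e-14), GATA3-positive and Helios-positive Treg (6 of 11, 2.696e-05), aryl hydrocarbon receptor (3 of 6, 1.064e-05) and Th2 genes (5 of 6, 0.00141) were called higher with the preset correlation and stood at 0.0759, 0.0819, 0.0774 and 0.0774 with an estimated correlation. Camera also called higher, with the preset correlation only, cholesterol (5.017e-05, 0.469 estimated), glycolysis (0.00141, 0.255) and TGF-beta genes (0.00141, 0.269). The same held for Treg identity (0.00596, 0.378), plasma cell (2.314e-04, 0.306) and epithelial genes (0.0355, 0.406). Fry called all of these lists higher too (adjusted p from 0.00115 to 0.024). It also called the effector Treg, GATA3-positive, aryl hydrocarbon receptor and Th2 lists higher (adjusted p from 3.351e-04 to 4.407e-04). Lower were the naive and lymphoid homing (12 of 17, 2.313e-09, 0.226 estimated), B cell (0.00106, 0.51) and type I interferon lists (0.0385, 0.584). By fry the naive list passed (adjusted p = 0.00356), and the B cell (0.0584) and interferon lists (0.059) did not. The interferon call ended without Maf-KO spleen replicate 2 (0.107) or Maf-KO gut replicate 3 (0.0677), and the epithelial call without Maf-KO gut replicate 3 (0.0586). Not called by camera were the follicular (0.176), oxidative phosphorylation (0.166), PI3K (0.468), cell cycle (0.962), STAT3 (0.77) and macrophage lists (0.77). The same held for the MHC class II (0.962), CD8 and NK (0.165), red cell (0.293), stroma (0.816) and pancreatic lists (0.478). Of these, fry called the CD8 and NK list higher (adjusted p = 0.0426). The CD8 and NK list was called without Maf-KO spleen replicate 2 (0.0188) and the red cell list without Maf-KO gut replicate 2 (0.0261). The cell cycle, MHC class II, CD8 and stroma lists had a median, a mean or a test direction of differing sign.

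**Figure D4:**
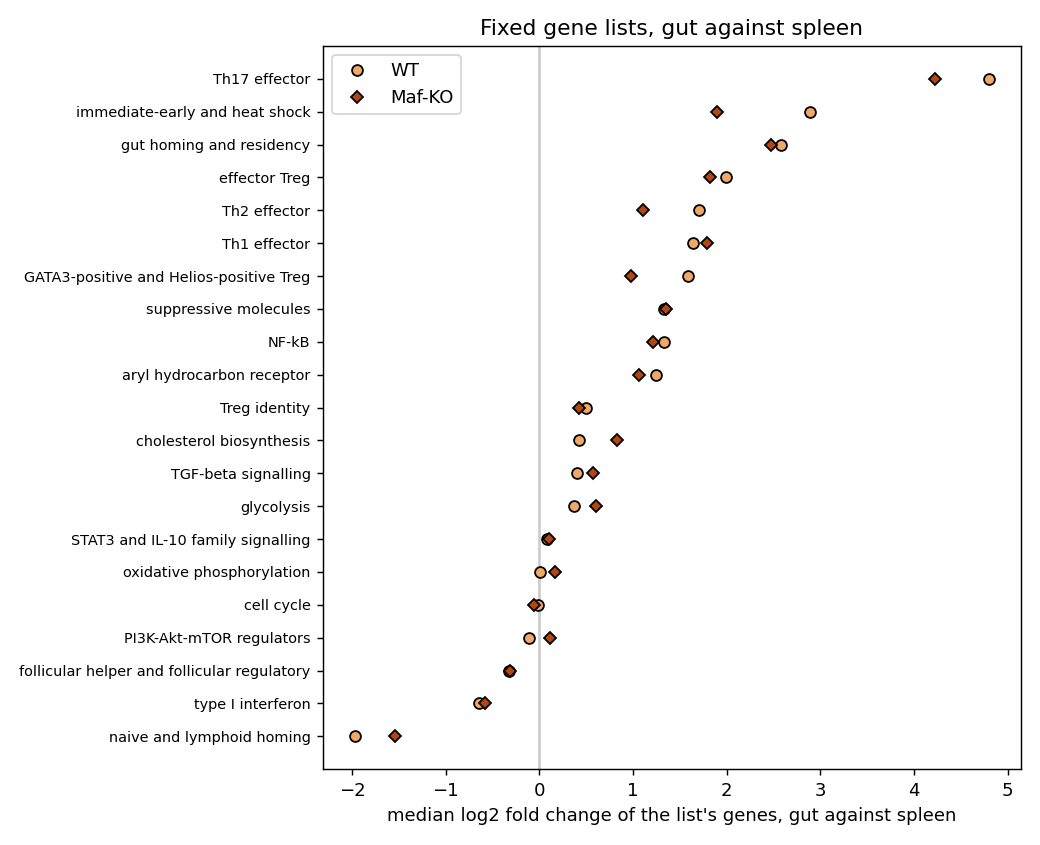
Median log2 fold change between gut and spleen (horizontal axis) of the genes in each of 21 fixed lists (vertical axis), with circles for WT and diamonds for Maf-KO. The Th17 list has the highest median in both genotypes (4.80 in WT and 4.22 in Maf-KO) and the naive and lymphoid homing list the lowest.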

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

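Of the tests in this part, the weighing of Maf loss against pancreatic RNA was chosen after the result was seen.

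The genotype effect on 6 gene lists differed between gut and spleen by camera with its preset correlation, a test of the difference itself. These were pancreatic acinar genes (adjusted p = 1.365e-12), naive and lymphoid homing genes (0.00813) and oxidative phosphorylation genes (0.00813). The genotype effect was more positive in gut than in spleen for 14 of 17 naive genes (median difference 0.43). For oxidative phosphorylation that was so in 19 of 22 (median 0.15). The others were STAT3 and IL-10 family genes (0.0402, 7 of 12, median 0.22), GATA3-positive and Helios-positive Treg genes (0.0496, 2 of 11, median -0.32) and glycolysis genes (0.0496, 14 of 18, median 0.17). With an estimated correlation the pancreatic list stood at an adjusted p of 0.322 and the others at 0.787, and fry gave 0.878 for each.

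Each of the 6 calls ended when single libraries were left out. The pancreatic list was at 0.209 without Maf-KO spleen replicate 1. The naive list was at 0.984 without WT gut replicate 1, 0.908 without Maf-KO gut replicate 3, where its mean log2 change turned to -0.07, and 0.204 without Maf-KO spleen replicate 1. Oxidative phosphorylation was at 0.481 without WT gut replicate 3, 0.201 without Maf-KO gut replicate 3 and 0.0906 without WT spleen replicate 2. The GATA3 list was at 0.221 without WT gut replicate 3, 0.287 without Maf-KO gut replicate 2, 0.149 without WT spleen replicate 1 and 0.567 without Maf-KO spleen replicate 1. Glycolysis was at 0.254 without WT gut replicate 1, 0.282 without Maf-KO gut replicate 3, 0.0999 and 0.142 without WT spleen replicates 2 and 3 and 0.0916 and 0.14 without Maf-KO spleen replicates 2 and 3. The STAT3 list was at 0.13 and 0.0953 without WT gut replicates 1 and 3, 0.282 without Maf-KO gut replicate 3, 0.066 and 0.0706 without WT spleen replicates 2 and 3 and 0.0998 without Maf-KO spleen replicate 2. With the title number as a block, chosen for lists after the data were seen, the pancreatic (0.209), naive (0.508), oxidative phosphorylation (0.209), STAT3 (0.183) and GATA3 lists (0.236) were not called.

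Transcripts of pancreatic acinar cells were found in WT gut, with 215 and 64 counts of Pnlip and 213 and 30 of Cela2a in replicates 1 and 3 and 0 in Maf-KO gut, in cells sorted as CD4 T cells, while Maf-KO spleen replicate 1 held 9 of each, WT spleen replicate 1 held 3 and 4 and the other spleen libraries 0. Of 16 other acinar genes, listed before they were looked up, 14 (87.5%) were higher in WT gut replicate 1 than in every library outside WT gut, so RNA of acinar cells is a candidate source. The genes called lower in Maf-KO gut did not follow this RNA. Over 17 of them the ratio of WT gut replicate 1 to replicate 3 had a median of 1.06 (0.622 to 1.67), against 5.66 for the 5 acinar genes summed. A call favours genes whose replicates agree, and Pnlip, with 0 counts in Maf-KO gut, was not called (edgeR adjusted p = 0.142). A low ratio was thus favoured by the selection and is not an independent test of pancreatic RNA behind the calls. The ratio of 5.66 between libraries of 1 genotype and the low counts in a Maf-KO spleen library, with 43 of Prss2 against 14 to 25 in the other spleen libraries, show that genotype alone does not set the level, but with 2 libraries per group a part of Maf loss in the acinar difference cannot be told apart from differences between single libraries.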

How the results depend on the processing

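All alternatives were fixed before the data were examined, except 6 that were added after seeing the data: counts without TMM factors and log2 values less the TMM factors for tissue comparisons, the genes of the log2 files only, title number as a random effect for tissue comparisons, the overlap under the same settings, and the title-number block for lists. For each setting below, the cause of the change was not tested unless it is named.

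Against 20 genes called in gut, 74 (22 higher and 52 lower) were called without the filter on low counts, 112 with DESeq2 (36 higher and 76 lower), 33 with limma-voom (5 and 28), 42 with title number as a random effect (5 and 37), 12 with gut libraries alone (3 and 9) and 9 with a block on replicate number (1 and 8). Of the 20, the fits kept 20, 20, 17, 20, 7 and 8 in that order. Against 2 in spleen, 12 were called without the filter, 19 with DESeq2, 5 with limma-trend on the log2 values, 1 with spleen libraries alone, 0 with limma-voom (320 unadjusted) and 0 with title number as a random effect (307 unadjusted). The overlap of 2 genes became 8, 13, 4, 1, 0 and 0 in the same order. DESeq2 called 8 interaction genes where edgeR called 0, with 422 unadjusted. Between tissues the higher and lower calls moved from 1942 and 1761 to 1163 and 3698 in WT and from 1906 and 1868 to 1082 and 3442 in Maf-KO with limma-trend on the log2 values. Counts without TMM factors gave 1327 and 3938 in WT and 1243 and 3701 in Maf-KO, and the log2 values less the TMM factors 1773 and 1703, and 1751 and 1741, so the scaling is the cause of this move. Gut against spleen in Maf-KO moved from 3774 to 5778 with title number as a random effect. With DESeq2 size factors the counts were 18 in gut, 2 in spleen, 3662 and 3725 between tissues and 0 for the interaction, and with the genes of the log2 files alone 21, 3, 3468, 3539 and 0. Limma-trend on the log2 values called 15 genes in gut.

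Leaving out 1 library gave 4 (without either Maf-KO gut replicate) to 22 genes in gut (without WT spleen replicate 3), with 0 to 7 higher and 3 to 19 lower, 2 to 9 in spleen (9 without WT spleen replicate 2, 5 higher and 4 lower), 2183 to 3597 between tissues in WT (lowest without WT gut replicate 1) and 2118 to 3785 in Maf-KO (lowest without Maf-KO gut replicate 3). The interaction stayed at 0 in each case by edgeR, and the overlap was 2 to 7 (7 without WT spleen replicate 2). A fit with fewer libraries in a group of 2 has less information by construction.

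No called gene that the naming rule took turned its direction under any alternative, and the 7 gut genes named in addition were not traced through the alternatives. Blocks on the title number changed no calls of named genes and lists other than those given here and beside the results, apart from the red cell genes Slc4a1 (0.0261) and Hbb-b1 (0.0222), which the block called lower in WT gut than in spleen. Mean log2 changes of some lists turned sign, the following among them. The epithelial list in gut was at 1.21 with the replicate-number block. The macrophage list in gut ranged from -1.35 (without Maf-KO gut replicate 2) to 0.73 (without WT gut replicate 3) and was called in the other direction at -0.11 without Maf-KO gut replicate 3. In spleen it ranged from -1.22 (without Maf-KO replicate 2) to 0.18 (without WT replicate 3). The cell cycle list in spleen ranged from -0.23 (without WT replicate 3) to 0.21 (without Maf-KO replicate 3). The naive list of the interaction was at -0.07 without Maf-KO gut replicate 3 and the follicular list at 0.65 with the title-number block. That block also called the interaction for Treg identity (0.0171), gut homing (0.0171), immediate-early (2.402e-04), B cell (0.0496), macrophage (3.370e-04) and MHC class II lists (0.00108). The replicate-number block ended the gut calls of the Th17 (0.117), follicular (0.2), glycolysis (0.0584) and oxidative phosphorylation lists (0.0562), and in spleen it added NF-kB (0.0212). For the interaction it ended GATA3 (0.119), naive (0.101), glycolysis (0.0983) and STAT3 calls (0.0983), and DESeq2 size factors ended those of GATA3 (0.0501) and glycolysis (0.053).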

Other observations

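The tests of neighbouring genes and of Igha in this part were chosen after the results were seen, and the Igha tests replaced earlier ones whose results were known and whose genes lay at the floor or had high baselines. The split of the spleen libraries was planned before the data were examined.

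All 10 libraries had a male pattern of expression, with 0 to 2 counts of the female-specific RNA Xist and 1605 to 3736 of the Y-linked gene Ddx3y. The myeloid list took 0.0198 to 0.108% of the counts in spleen and 0.0119 to 0.035% in gut, and B cell genes 0.0229 to 0.0629% in spleen against 0.0104 to 0.0139% in gut. Epithelial genes took 0.0139 to 0.0159% in gut and 0.00379 to 0.00771% in spleen. Epcam gave 989 to 1494 counts in each gut library and 271 to 614 in each spleen library. This share therefore leans on Epcam and is no measure of epithelial cells by itself.

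Among the 20 genes called in gut, 3 pairs lie within 100 kb of each other, Rnase4 with Ang, Neb with Arl5a and Laptm4b with Matn2. Random sets of tested genes held 0.062 pairs on average (permutation p = 1.700e-04, 100000 sets). Without Rnase4 and Ang, whose counts may not be separate, 2 pairs remain, and a share of 0.00176 of the random sets held 2 or more. Among the 69 genes at an unadjusted p under 0.001 were 5 pairs against 0.758 (permutation p = 0.0015). None of the pairs lies on the chromosome of Maf (0 pairs), which argues against DNA linked to the targeted locus, and within 10 Mb of Maf 9.36% of genes had an unadjusted p under 0.05 in gut against 8.13% elsewhere (Fisher's exact p = 0.572) and 3.51% against 2.84% in spleen (0.491). The models of Rnase4 and Ang share 10933 base pairs, so shared reads cannot be told apart from a change of both, while the other pairs are at least 22385 base pairs apart. The log2 change of Neb minus that of Arl5a was -1.28 (SE 0.29) in spleen, which argues against read-through there, but -0.37 (SE 0.34) in gut, and for Matn2 and Laptm4b it was -0.80 (SE 0.44) in gut and -0.78 (SE 0.32) in spleen. Read-through therefore stays open for both pairs in gut, and a shared response of neighbours to c-Maf is a hypothesis that was not tested.

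The change of Igha in Maf-KO spleen was 1.75 (SE 0.44, edgeR adjusted p = 0.999; exact permutation p = 0.1, the smallest possible), with each Maf-KO library above each WT library, and its change in gut was -0.59 (SE 0.51, edgeR adjusted p = 0.824). Carry-over of RNA from Maf-KO gut libraries would need 1.23% of their level and would add 146 CPM over Atf3, Gzma, Gzmb, Hspa1a and Hspa1b. The excess seen was 20.5 CPM (SE 28.0), with Gzma at -2.00 against 53.1 and Gzmb at 1.64 against 40.7. This argues against carry-over from Maf-KO gut, and carry-over from WT gut was not tested. RNA of IgA plasma cells, which the sort should remove, would add 27.4 CPM of Jchain at the Jchain to Igha ratio of Maf-KO gut. The excess was 15.4 CPM (SE 22.7), which leaves this source open. The genotype of the mice stays an open, untested explanation.

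Of the 10 splits of the spleen libraries into 3 and 3, the real one and 1 other called 2 genes each, so 2 splits reached the real count when the real one is included (2 in the highest of the others). So few splits cannot give a share under 0.05. At an unadjusted p under 0.05 the real split had 376 genes, and 6 of the 9 others had more, 397 to 1668, so the real split does not stand out by this count.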
